A study of Mus musculus with 12 samples.

How the data were processed

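MNase-seq was analysed for 12 mouse samples in 6 groups of 2, from 2 stages and 3 amounts of MNase. Per the labels' protocols, cells were collected by STAPUT sedimentation from 11 mice aged 8 to 12 weeks per collection, to a purity of at least 85%, and digested for 7.5 min at 37 °C, with 2 times as many cells for the round spermatid fraction. The submitters' processing notes name STAR 2.5.2a and the genome build GRCm38/mm10. The nucleosome caller and its threshold are not given in the sources used here. Per the design text of the series, each list of calls was made by the authors from both replicates of a group, so replicates were not separate in the values analysed and their agreement was not analysed here.

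Each list holds intervals of 140 bp with a p-value that the authors deposited for each call, and no read counts. The p-values of a list take few distinct values. They were compared with upper tails of Poisson distributions by searching for the minimum count and the mean that match the 8 largest values, and every value of at least 1e-300 was then assigned the nearest tail. The largest difference of the natural logarithms was 1.06e-10, and the minimum was 6 reads in every list. Between 161 and 198 calls per list had smaller p-values and were assigned the next count. The resulting read counts and mean coverage are derived from the p-values, and the number of sequenced reads behind each list is unknown. With 65.4% to 69.5% of calls at the minimum, the presence of a single call depends on 1 read more or fewer, which limits statements on single genes. The p-values were used within a list to describe or filter calls.

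Calls were represented by their midpoints. Sex chromosome, gene and sharing analyses used 21 chromosomes, and calls on unplaced contigs were used only in list sizes, in the shares of calls by implied reads and in the shares of dense bins. Genes came from a RefSeq table of the same build with 49943 genes on these chromosomes, 21887 of them protein-coding. This table gives gene starts and ends but neither strand nor exons, and no genome sequence was used here. Promoters in the design were therefore replaced by windows of 1000 bp on each side of both gene ends, exons and introns were treated together as gene bodies, and random gene lists were matched on 10 classes of gene length in place of promoter CpG. A profile around transcription start sites and the base composition of calls were not analysed here.

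Random placement used 100 seeded circular shifts of the calls between the first and the last call of a chromosome. Enrichment is the observed number over the mean of the shifts, with ranges taken over the shifts. A position was shared when midpoints lay within 73 bp. Dense bins were 10 kb bins with more than 20 calls in any list. Density on X and Y was calls per bp between the first and last call, over the same for 19 autosomes. A coverage ratio is the Poisson mean, over that of the list, whose tail at the minimum of 6 reads gives the observed density; it rests on that model alone. Spacing was the mode of distances up to 1000 bp between 120 and 250 bp, in 10 bp bins summed over 3 bins, with intervals from 1000 Poisson resamples. Shares have exact binomial (Clopper-Pearson) 95% intervals, and log2 ratios have normal intervals from the counts. Overlapping calls are not independent, so these intervals cover counting error only and are too narrow.

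For 13 gene lists fixed before the data were examined (spermiogenesis, meiosis, spermatogonia, Sertoli and Leydig cells, histone acetylation, imprinted genes, developmental transcription factors, ribosomal proteins, replication-dependent histones, olfactory receptors, vomeronasal receptors, multicopy X and Y genes, and housekeeping genes), calls were counted at gene ends and over gene bodies with 1000 bp on each side. Counts were set relative to all protein-coding genes, with 0.5 added to observed and expected calls, and each list was placed among 10000 random lists. That is a description of these lists of calls, not a test of the stages. The gene body measure, the comparison at equal MNase per cell, and the use of merged calls outside list sizes were added after the data were seen. Named genes were 8 set in advance, the 10 genes per stage with end calls at most amounts of that stage and in no list of the other, ranked by amounts, then by calls per 100000, then by symbol, and the 2 members of each gene list with the largest stage difference. One gene chosen by these rules is not reported here. Other names were chosen after their values were seen.

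Stages were compared at the same MNase amount, without a test, as the lists have no replicates. The only test was an exact permutation test of list size against implied coverage, two-sided. The steps were tested on simulated data: 29.9% of shared positions were recovered where 30% were planted, an enrichment of 3.05 at the ends of 21887 genes where 3 was planted, an X density of 0.25 where 0.25 was planted, a spacing of 205 bp where 200 bp was planted, and a log2 ratio of 0.74 for the meiosis list where 1 was planted. The inversion of p-values gave 0 wrong counts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

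Alternatives were other windows and distances, calls of more than 6 implied reads, autosomes alone, lists without dense bins, merged or thinned lists, each MNase amount left out, random gene lists without matching, and pairs at equal MNase per cell.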

Results

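Nucleosome positions were mapped by MNase-seq in male germ cells of SV129 mice. Micrococcal nuclease (MNase) digests the linker DNA between nucleosomes, so the fragments that survive mark DNA held by histones. The 12 samples came from 2 stages of spermatogenesis: a fraction titled meiotic spermatid in the labels and meiotic in their protocol, called M below, and a fraction labelled round spermatid, called RS, the haploid cells in which histones are later replaced by protamines. The title of M leaves open whether that fraction held meiotic cells or spermatids. Each stage was digested with 0.5, 1 or 2 U of MNase, with 2 samples per stage and amount. The authors called nucleosomes from both samples of a group together, so 6 lists of calls were compared, without replicate lists. No difference between stages could therefore be tested against replicate error. The 3 amounts are not replicates, and a two-sided sign flip over them could not give a p below 0.25. The intervals below are 95% intervals for counting error only, and because neighbouring calls overlap they are narrower than independent positions would give.

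The first question was how many positions each digestion gave. The lists of M held 42178 calls at 0.5 U, 60077 at 1 U and 65614 at 2 U. Those of RS held 179133, 41655 and 27101 calls. The lists thus grew with MNase in M and shrank in RS. The ratio of RS to M was 4.25 at 0.5 U, 0.693 at 1 U and 0.413 at 2 U. RS had been digested with 2 times as many cells at each amount, and at equal MNase per cell the ratios were 0.988 (RS at 1 U over M at 0.5 U) and 0.451 (RS at 2 U over M at 1 U).

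Every call spanned 140 bp and carried the authors' p-value. The p-values matched Poisson tail probabilities with a minimum of 6 reads in every list, which gave the read count that each p-value implies and the mean coverage of each list. This mean was 0.434, 0.484 and 0.507 reads per window in M and 0.696, 0.472 and 0.409 in RS, from 0.5 to 2 U. Most calls stood at the minimum: between 65.4% and 69.5% of a list had exactly 6 implied reads. Calls of 10 or more reads made up 7.36%, 6.48% and 6.48% of the M lists and 3.35%, 8.33% and 11.3% of the RS lists. The logarithm of the number of calls followed the implied coverage over the 6 lists (Pearson r = 0.975, exact permutation p = 0.00278, adjusted p = 0.00556; Spearman rho = 0.943, exact permutation p = 0.0167, adjusted p = 0.0167; 2 coefficients computed). Without the 2 lists farthest from the median coverage, r was 0.825 over 4 lists (exact permutation p = 0.167; the fewer lists and narrower range leave this check little power). A rise of calls with coverage is expected where every list has the same minimum of 6 reads, so these p-values say little about its cause.

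**Figure D1:**
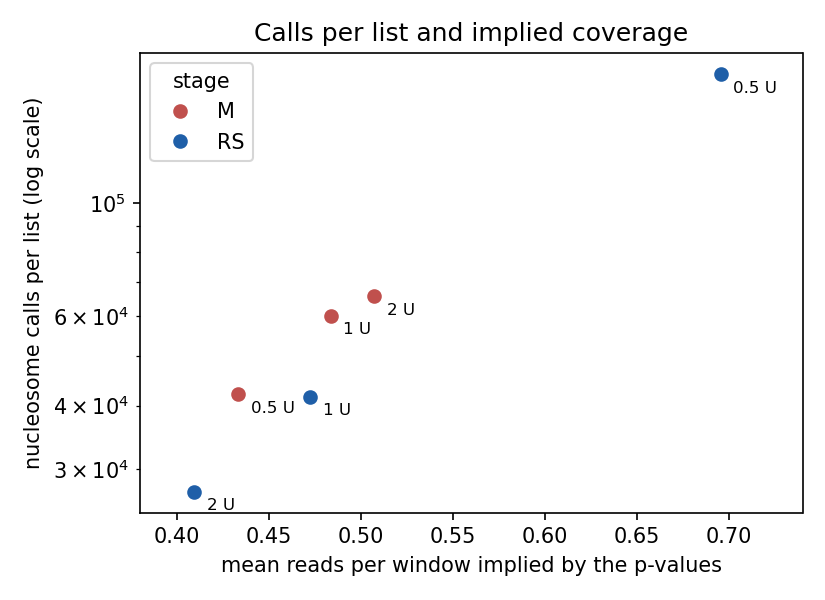
Number of nucleosome calls per list (log scale) against the mean reads per window that the p-values imply; each point is 1 list, coloured by stage and marked with its MNase amount. RS at 0.5 U lies highest on both axes, with 179133 calls, and RS at 2 U lowest on both, with 27101.

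The next comparison asked whether the same positions were called in different lists. Over the 15 pairs of lists, 11.2% to 21.6% of the calls of the smaller list had a call midpoint of the other list within 73 bp, against 0.161% to 0.761% after random shifts. The geometric mean of the fold over random was 44.5 within a stage and 44.5 between stages at the same MNase amount. Between stages at different amounts it was 45.3. By this fold, lists of 1 stage shared no more positions than lists of different stages. The mean share was 15.5% within a stage, 16.3% between stages at the same amount and 14.3% between stages at different amounts. Pairs within a stage always differ in amount, and the fold depends on list size. These means therefore do not settle whether a common stage adds to sharing. Sharing rose with the implied reads of a call. Calls of 6 reads were shared in 3.55% to 9.67% of cases, those of 7 reads in 11.1% to 26.2%, those of 8 to 9 reads in 35.3% to 62.9%, and those of 10 or more reads in 84.3% to 97.4%. Of the 15985 merged positions of RS at 2 U, 604 (3.78%) were found in all 6 lists.

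Much of this sharing came from a few dense places. Of all 10 kb bins, 260 held more than 20 calls in at least 1 list, and 249 of these had calls in all 6 lists. Unplaced contigs, with 22 of these bins, included, they held 17.05%, 15.1% and 14.6% of the calls in M and 7.74%, 18.95% and 23.8% in RS, and between 81.6% and 87.5% of the calls of 10 or more reads. Without them, 125 of 14292 merged positions of RS at 2 U (0.875%) were in all 6 lists, and the fold over random was 14.8 within a stage and 15.0 between stages. Sharing by implied reads was not computed without the dense bins. The high share of calls of 10 or more reads therefore cannot be taken to hold for the rest of the genome. On GRCm38/mm10, the 10 kb bins at chromosome 13 from 12790001 to 12950000, around the prolactin family member Prl2c3, held 775, 906 and 892 calls in M and 1586, 681 and 409 in RS. The bins at chromosome 11 from 3120001 to 3200000, around Sfi1 and the pseudogene Pisd-ps1, held 548, 714 and 784 calls in M and 847, 730 and 682 in RS. The bin at chromosome 17 from 39840001 to 39850000, which carries the ribosomal RNA-like gene Rn18s-rs5, held 134, 159 and 168 calls in M and 163, 160 and 163 in RS.

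Calls were then placed relative to genes. Fewer calls than the mean of random shifts lay within the bodies of protein-coding genes in each of the 6 lists, and M was lower than RS at each amount. Observed over random, gene bodies held 0.719, 0.782 and 0.837 of the expected calls in M and 0.864, 0.892 and 0.909 in RS, from 0.5 to 2 U. For RS at 2 U the range over random shifts, 0.806 to 1.02, included 1, and for the other lists it lay below 1. The mean log2 ratio of RS to M was 0.19 (0.17 to 0.21). For intergenic sequence it was -0.10 (-0.12 to -0.09). Windows of 1000 bp on each side of a gene end held 0.817, 1.09 and 1.32 times the expected calls in M and 0.908, 1.22 and 1.26 times in RS. Enrichment at gene ends was thus higher at 2 U than at 0.5 U in both stages, by a log2 ratio of 0.69 in M and 0.47 in RS. The ranges over random shifts were wide, from 0.929 to 1.65 for RS at 2 U. Between stages the log2 ratio at gene ends was 0.15, 0.16 and -0.07 at the 3 amounts (mean 0.08, 0.02 to 0.14). This sign depended on the window, with a mean of -0.11 for windows of 500 bp, so no difference between the stages was established at gene ends.

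The gene content of larger regions showed the same order. On autosomes outside the dense bins, the 282 bins of 1 Mb in which no protein-coding gene starts held 1.63 times the mean number of calls in M at 0.5 U (1.59 to 1.66), 1.28 times at 1 U and 1.06 times at 2 U. In RS they held 1.27, 1.02 and 0.929 times the mean. The 244 bins with more than 20 genes held 0.534, 0.673 and 0.785 times the mean in M and 0.751, 0.846 and 0.907 times in RS. Calls in gene-poor bins were thus relatively more frequent in M than in RS at each amount, and became less so with more MNase in both stages. Across amounts, bins without genes were close for RS at 0.5 U and M at 1 U (1.27 and 1.28). The same held for RS at 1 U and M at 2 U (1.02 and 1.06). In bins with more than 20 genes RS stayed higher in these pairs (0.751 against 0.673, and 0.846 against 0.785). The stage difference in gene-poor bins therefore cannot be told apart from a difference in the extent of digestion.

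**Figure D2:**
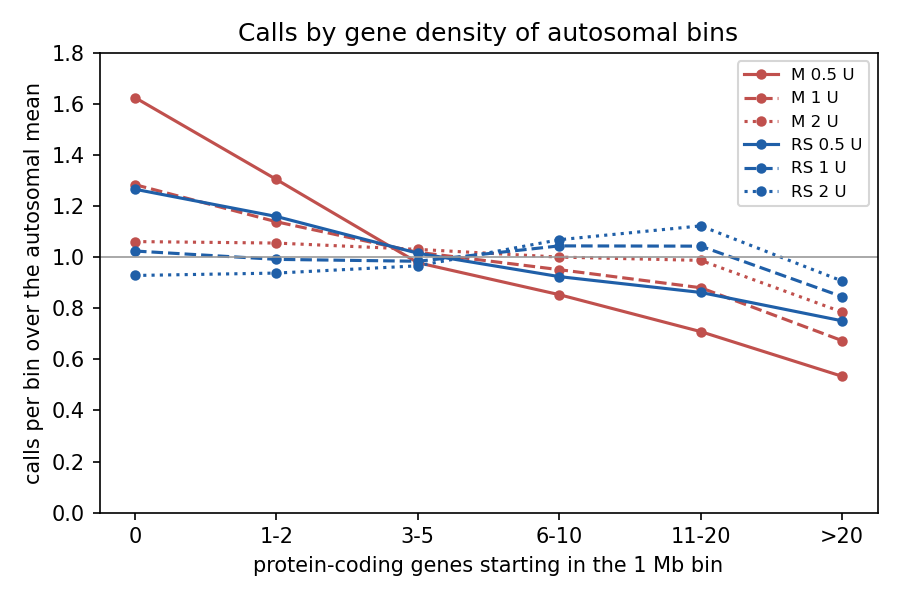
Calls per 1 Mb bin of the autosomes, over the mean of all such bins in the same list, against the number of protein-coding genes that start in the bin; lines are the 6 lists, coloured by stage, with 1 line style per MNase amount. Bins without genes held 1.63 times the mean in M at 0.5 U and 0.929 times in RS at 2 U.

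The X chromosome differed between the stages more than any autosome. Its calls per bp, over those of the autosomes, were 0.317 (0.296 to 0.339), 0.199 (0.185 to 0.213) and 0.155 (0.144 to 0.168) in M from 0.5 to 2 U. In RS they were 0.0608 (0.0565 to 0.0653), 0.0693 (0.0598 to 0.0800) and 0.0890 (0.0755 to 0.104). The relative density of X was therefore higher in M at each amount, by 5.21-fold, 2.87-fold and 1.75-fold, with a mean log2 ratio of RS to M of -1.57 (-1.69 to -1.45). The corresponding mean for single autosomes ran from -0.17 on chromosome 3 to 0.21 on chromosome 11. The density on X lay below that of the autosomes in each list. A Poisson model with 0.5 of the autosomal coverage gave 0.0186 to 0.0210, lower than the X density of each list. Because calls are a tail above a minimum, their density changes more than coverage does. Under the same model the X coverage over that of the autosomes was 0.816, 0.751 and 0.719 in M and 0.603, 0.625 and 0.655 in RS, a much smaller difference than that of the calls. The model did not give the sizes of the lists. For 2 U over 0.5 U its tails gave 2.41 in M and 0.0530 in RS, against 1.56 and 0.151 observed. These coverage ratios are therefore values of the model and not measured coverage. The Y chromosome had few calls, with relative densities of 0.0626, 0.0488 and 0.0633 in M and 0.0130, 0.0581 and 0.0628 in RS. At 1 U and 2 U the Y intervals of the stages overlapped.

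**Figure D3:**
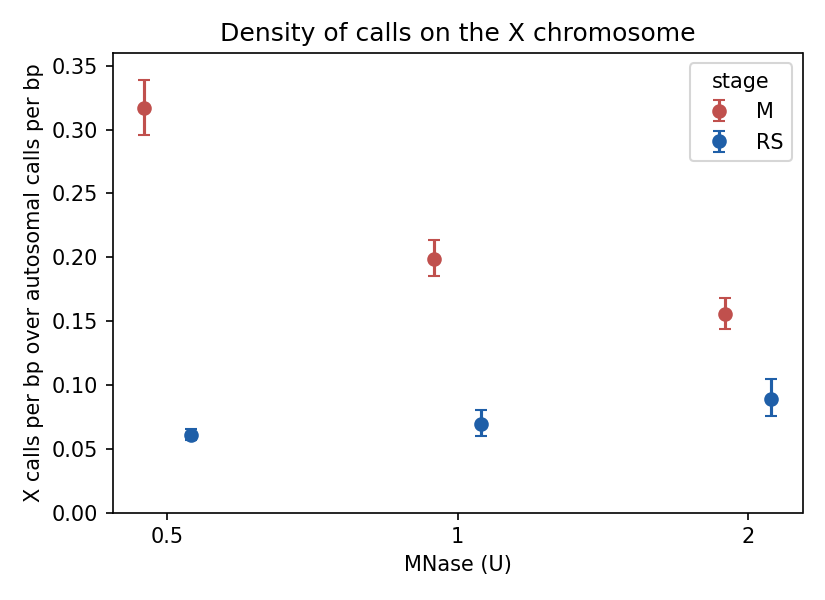
Calls per bp on the X chromosome over calls per bp on the autosomes, by MNase amount and stage; points are single lists and bars are exact binomial 95% intervals for counting error. The M values lie between 0.155 and 0.317 and the RS values between 0.0608 and 0.0890.

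Distances between all pairs of calls up to 1000 bp apart gave spacings whose intervals overlapped between the stages at each amount. The most frequent distance between 120 and 250 bp was 185 bp (165 to 205), 165 bp (165 to 185) and 175 bp (155 to 175) in M. In RS it was 195 bp (165 to 215), 175 bp (155 to 185) and 165 bp (145 to 195). Without dense bins it was 165 bp in RS at 1 U and 145 bp in RS at 2 U, and the same in the other lists. A difference in this spacing between the stages was not detectable at this depth. Whether the distances peaked above a background was not tested, so these modes need not be nucleosome repeat lengths.

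Genes of the germ cell programme were compared through lists fixed before the data were examined. Over gene bodies, a measure chosen after the data were seen, the spermiogenesis list had 35 calls in M and 107 in RS, and its density relative to all protein-coding genes was higher in RS at 3 of 3 amounts. The mean log2 ratio was 1.07 (0.48 to 1.66), at percentile 98.7 of 10000 random lists matched on gene length. Of its 50 members, 19 had more calls in RS per 100000 calls, 9 had more in M and 22 had no call in any list. Of all 21887 protein-coding genes the numbers were 8415, 5572 and 7900, so 60.2% of the genes with calls had more in RS, against 67.9% of the members. The largest differences, named after their values were seen, were at Zpbp, which encodes a protein of the acrosome, with 1 call in M and 17 in RS, and at Spata16, another acrosome gene, with 4 and 14. Odf2, of the outer dense fibres of the sperm tail, had 0 and 9.

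The meiosis list had 49 calls in M and 159 in RS, also with a higher relative density in RS at 3 of 3 amounts (mean log2 ratio 0.73, 0.19 to 1.26; percentile 98.2). Of 50 members, 29 had more calls in RS per 100000 calls, 11 had more in M and 10 had no call in any list. Mei4, which is needed for meiotic double-strand breaks, had 11 calls in M and 35 in RS, and without it the mean log2 ratio was 0.41 (-0.26 to 1.09). The helicase gene Hfm1 had 2 calls in M and 11 in RS. Tex14, of the bridges between germ cells, went the other way with 2 and 0 calls. With calls of more than 6 implied reads alone, the meiosis ratio was -0.09 (-1.33 to 1.15).

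Other gene lists were compared in the same way. The 353 vomeronasal receptor genes had a log2 ratio of RS to M of -0.54 (-0.78 to -0.31; percentile 0.23) and were higher in M at 3 of 3 amounts. Single members went both ways: 80 had more calls in M per 100000 calls, 73 had more in RS and 200 had no call in any list. Vmn2r30 had 29 calls in M and 13 in RS, while Vmn2r23 and Vmn2r111, named after their values were seen, had 1 and 8 calls and 8 and 23. With calls of more than 6 implied reads alone, the vomeronasal ratio was -0.16. Olfactory receptor genes had a ratio of -0.56 (-0.82 to -0.30; percentile 6.64), but were higher in M at only 2 of 3 amounts, and the ratio was -0.21 without 2 U and -0.88 without 0.5 U. The developmental transcription factor list had a ratio of 0.45 (0.07 to 0.83; percentile 92.2), higher in RS at 2 of 3 amounts, and 0.11 without 0.5 U and 0.75 without 2 U. The histone acetylation list, which includes Kat2a (Gcn5), had 0.60 with an interval that includes 0 (-0.12 to 1.32). Intervals also included 0 for genes of spermatogonia (-0.53, -1.08 to 0.03), of Sertoli and Leydig cells (-0.07, -0.69 to 0.54), imprinted genes (-0.41, -0.87 to 0.06), ribosomal protein genes (0.17, -0.82 to 1.16), replication-dependent histone genes (0.18, -0.87 to 1.23), multicopy X and Y genes (-0.18, -1.45 to 1.10) and housekeeping genes (0.58, -0.51 to 1.66). The Sertoli and Leydig ratio was 0.76 without the member that differed most and 0.70 with calls of more than 6 implied reads, and that of spermatogonia -0.87 without 0.5 U, so these lists for other testis cells do not settle whether the fractions differ in such cells. Percentiles depended on the matching of gene length: without it they were 0 for olfactory receptors and 99.4 for developmental transcription factors. Random lists drew single genes and were not matched on the gene content of the region. Several vomeronasal receptor genes lie close together on chromosomes 7 and 17, and such neighbours may not be independent. The percentiles of lists with clustered members can therefore be too extreme.

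**Figure D4:**
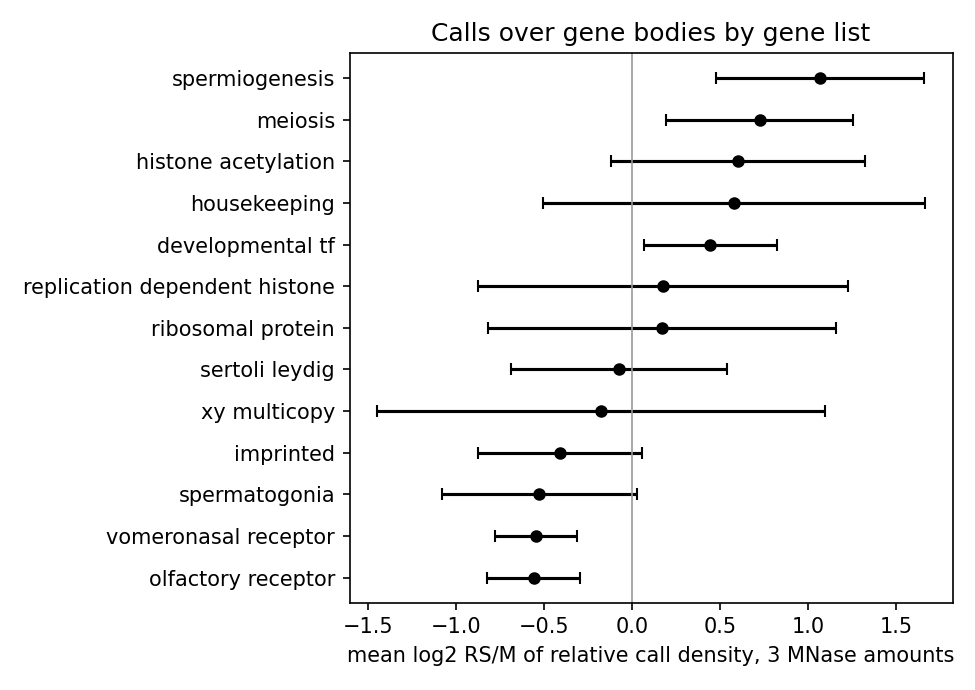
Mean log2 ratio of RS to M of the density of calls over gene bodies, relative to all protein-coding genes, for 13 gene lists; points are means over 3 MNase amounts and bars 95% intervals for counting error. The spermiogenesis list is highest at 1.07, and the olfactory and vomeronasal receptor lists lie at -0.56 and -0.54.

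Few calls lay at the ends of single genes. The protamine genes Prm1 and Prm2, the transition protein genes Tnp1 and Tnp2, the synaptonemal complex gene Sycp3 and the acetyltransferase gene Kat2a had 0 calls within 1000 bp of either end in each of the 6 lists. Sycp1 had 3 calls and the bromodomain gene Brdt 1 call, in RS at 0.5 U only. At gene ends, the measure planned for the gene lists, the spermiogenesis list had 7 calls in M and 8 in RS, and the meiosis list 1 and 13, with intervals of the log2 ratio that include 0. Of the 13 lists, only the olfactory receptors (-0.59, -0.90 to -0.27; percentile 6.90) and the vomeronasal receptors (-0.62, -1.20 to -0.03; percentile 11.1) had end intervals that exclude 0, each higher in M at 2 of 3 amounts. The developmental transcription factors had 0.96 (-0.03 to 1.95; percentile 97.4), higher in RS at 3 of 3.

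Genes with end calls in a single stage were mostly seen in a single list. In M alone, 1944 genes had end calls at 1 amount, 132 at 2 amounts and 4 at 3 amounts. In RS alone the numbers were 2923, 161 and 7. These numbers were not adjusted for list size, and RS at 0.5 U held 179133 calls against 42178 in M. The larger numbers in RS therefore do not show that more genes belong to that stage. The 4 genes of M were Tctn2, a gene of the ciliary transition zone, with 10 calls, the RNA-binding protein genes Rbm47 and Lrpprc with 5 each, and Clrn1 with 3. The 7 genes of RS were Bspry with 8 calls, Vmn2r50 with 7, the blood group glycosyltransferase gene Abo with 6, Olfr847 with 6, and Taf6, Usp14 and Gm8300 with 4 each. The calls at Vmn2r50 lay in dense bins. Other ways of dividing the 6 lists into sets of 3 gave up to 28 such genes, against 11 for the stages. Lrr1, Zfp980, Col6a2, Cfap61, Crnkl1 and Mrpl2 followed in M, and Scgb2b6, Arsb and Muc13 in RS, each at 2 amounts.

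Among members of the gene lists, the largest stage differences at gene ends were also of few calls. Tekt1, of sperm flagella, had 3 calls in M and 0 in RS, and Gapdhs, the glycolytic enzyme of sperm, had 0 and 1. Hormad2 and Rad21l, of the meiotic chromosome axis, had 0 and 1 each. Among histone modifiers, Hdac1 had 2 and 0 calls and Kat8 1 and 1. Pou5f1 had 0 and 2, Foxo1 2 and 0, and Wt1, a Sertoli cell marker, 3 and 0. Acta2, Slc38a4, Dlk1, Dlx3, Nkx3-2, Rps23, Rplp2, H4c14, H2bc3, Olfr395, Spin2f, Rhox2f and Cct2 had between 0 and 4 calls in each stage. At these counts no difference between the stages was detectable for a single gene.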

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

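The tests in this part were chosen after the results they bear on were seen. The number of calls and the X density each moved with MNase in opposite directions in the 2 stages. These differences were not tested, as each stage and amount has 1 list.

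The log2 ratio of calls at 2 U over 0.5 U was 0.64 in M and -2.72 in RS. Sequencing depth is a candidate explanation that the values are in line with: calls and implied coverage had a Spearman correlation of 0.943 over the 6 lists. With a fixed minimum of reads a rise with coverage is expected, and the number of sequenced reads is unknown, so this supports depth only as far as implied coverage stands for it. Poisson tails at the implied coverage alone gave ratios of 2.41 in M and 0.0530 in RS, against observed ratios of 1.56 and 0.151, so the direction followed coverage and the size was smaller. Release of nucleosomes by MNase cannot be told apart from depth, because amount and implied coverage had the same or exactly opposite order in 2 of 2 stages. The stage itself stays open as an untested biological difference.

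The log2 ratio of the X density at 2 U over 0.5 U was -1.03 in M and 0.55 in RS, and the density was higher in M at each amount. Within each stage the X density fell as implied coverage rose. In M it was 0.317, 0.199 and 0.155 at 0.434, 0.484 and 0.507 reads per window. In RS it was 0.0890, 0.0693 and 0.0608 at 0.409, 0.472 and 0.696. The opposite directions with MNase therefore cannot be told apart from the opposite order of coverage, and do not show a response to MNase that differs by stage. Library depth as the whole cause was argued against by the pair closest in implied coverage, M and RS at 1 U (0.484 and 0.472 reads per window), where the X log2 ratio of RS to M was -1.52 (-1.75 to -1.29). MNase per cell alone was argued against in the same way, since pairs matched on it gave -1.68 (-1.84 to -1.51). These pairs need not match MNase per amount of DNA, because RS cells are haploid and the cell type of M is open. They therefore cannot decide whether the extent of digestion contributed. For any pairing of amounts X was denser in M: the lowest M value was 0.155 and the highest RS value 0.0890. Autosomal 1 Mb bins weighted to the gene counts of X bins gave only -0.037 (-0.046 to -0.027), so few genes per Mb do not account for the size, and 17 of the 17 segments of 10 Mb on X with at least 20 calls were higher in M. Base composition was not tested, and chromatin of the X chromosome that differs between the stages remains an untested hypothesis, as does any difference between the pooled animals.

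Calls on 1 unplaced contig, which the comparisons of chromosomes and genes did not use, numbered 1485, 1729 and 1758 in M and 1836, 1722 and 1655 in RS, from 0.5 to 2 U, a signal in sequence outside the main measurement.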

How the results depend on the processing

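Settings at equal MNase per cell, merged calls outside list sizes, and alternatives for gene bodies other than the window at gene ends were chosen after the data were seen. Of 88 alternatives of the main results, 67 stayed within the counting interval or within 1.5 times, 17 moved and 4 changed direction. A change of sign was counted as a change of direction only for ratios whose interval excludes no difference. The gene-end ratio of the spermiogenesis list, for example, went from -0.006 to 0.44 without 0.5 U and was counted as staying within its interval. The cause was not tested unless stated. At equal MNase per cell, the ratio of calls of RS to M went from 4.25 to 0.988 and from 0.693 to 0.451, the gene-end log2 ratio from 0.08 to 0.39, and the gene-body ratio from 0.19 to 0.26. The gene-end ratio was -0.11 with windows of 500 bp, 0.18 with 2000 bp, -0.024 with calls of more than 6 reads and 0.15 without 2 U. The gene-body ratio was 0.16 with calls of more than 6 reads, 0.16 without 0.5 U and 0.23 without 2 U, and stayed above 0 in 10 of 10 alternatives. The fold of sharing within and between stages was 102.5 and 101.7 at 20 bp, 26.4 and 26.4 at the widest distance, as the random share grows with the distance allowed, and 14.8 and 15.0 without dense bins. The X log2 ratio was -1.16 without 0.5 U and -1.95 without 2 U, and ran from -1.95 to -1.16 over 7 alternatives. With calls of more than 6 reads, the spermiogenesis ratio was 2.58 and the meiosis ratio -0.090, where calls were few. The chromosome 17 block had a log2 ratio of 2.40, and 2.11 with edges from the mean of the lists, an alternative chosen after the data were seen. Of 167 alternatives for other gene lists and the chromosome 17 block, 20 moved and 0 changed the direction of a ratio whose interval excludes 0.

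Stages were compared within each MNase amount, but no analysis paired by replicate was possible because the lists pool both replicates of each group, and for the same reason leaving out a replicate was not possible. Random placement matched on GC, 1 start site per gene, unique sequence length, the profile around start sites and base composition were not run, as no strand or sequence was used. With most calls at the minimum of 6 implied reads, depth limits all values for single genes.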

Other observations

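The tests in this part were chosen after the results they bear on were seen.

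A block of chromosome 17 from 30500001 to 30900000 (GRCm38/mm10) had more calls in RS. It was found from the data, as the autosomal 250 kb window with the most calls among those higher in every list of RS than in any of M, extended in steps of 50 kb with at least 10 calls and at least 2 times more in RS over the pooled calls of each stage. The first edge depends on the pooling: the step before it, with 11 calls in M and 29 in RS, was 1.64 times higher in RS over pooled calls and 2.39 times by the mean of the lists, which would start the block at 30450001. The block covers Glo1, which encodes glyoxalase 1, Dnah8, a dynein heavy chain of the sperm tail, and part of Btbd9. Its density over the autosomal mean was 0.886 (0.288 to 2.07), 1.56 (0.833 to 2.67) and 1.42 (0.756 to 2.43) in M and 5.86 (4.98 to 6.84), 10.1 (7.63 to 13.1) and 11.8 (8.45 to 16.1) in RS, from 0.5 to 2 U. Under the Poisson model of the calls, these densities correspond to a coverage over that of the autosomes of 0.979, 1.08 and 1.07 in M and 1.40, 1.52 and 1.56 in RS. That model did not give the sizes of the lists, so these are not measured coverage. The flanks of 1 Mb on each side had densities of 0.319, 0.674 and 0.721 in M and 0.681, 1.30 and 1.30 in RS, so the block lay above its flanks in M as well, by less than in RS. Over gene bodies, Dnah8 had 16 calls in M and 126 in RS, Btbd9 21 and 105, and Glo1 4 and 36. As the block was chosen for its difference, these values overstate it to an unknown degree.

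A change limited to Dnah8 was argued against by the 100 kb part of the block without that gene, where the log2 ratio of RS to M was 2.42 (1.45 to 3.39). This part lies in a window chosen for its ratio, which favours a high value. Dnah8 was also the gene with the most calls, 142, of 5 autosomal genes higher in RS when the limits of the window scan were applied to gene bodies, a choice that does not use this part. Of 24040 autosomal parts of 100 kb outside the block, 0 had a lower bound as high. This count adds little, because the other parts were not chosen for their ratio. A duplication in some of the pooled animals may account for the block, since duplications around Glo1 are known among laboratory mice. The higher of the 2 neighbouring 100 kb parts had a log2 ratio of 0.77, against at least 1.71 for each part inside, but the rule that set the edges favours such a step. A duplication cannot be told apart from a regional difference between the stages, because the labels do not say whether the fractions of the stages came from the same animals.

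Windows of 250 kb with at least 30 calls, a 4-fold difference and no overlap between the lists of the stages numbered 36. Of these, 7 autosomal windows and 3 on X were higher in M and 26 autosomal windows in RS. Of the 10 divisions of the 6 lists into sets of 3, 9 gave at least as many, and the highest other number was 97. For genes with end calls in all lists of a set and none of the other, 7 of the 10 divisions gave at least as many as the 11 of the stages, with a highest other number of 28. With 10 divisions no share under 0.05 can be had. Why other divisions gave larger numbers was not tested, and the lists differed in size from 27101 to 179133 calls.

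Other genes chosen after their values were seen were Sox6, with 7 calls over its body in M and 56 in RS, and the X-linked dystrophin gene Dmd, with 35 and 3. These counts were not adjusted for list size, and 41 of the Sox6 calls in RS came from the list at 0.5 U. The dense bin on chromosome 1 from 24610001 to 24620000, with Gm10222 and Gm10925, had fewer calls with more MNase in both stages: 124, 75 and 12 in M and 113, 4 and 0 in RS. A dense bin in Myo3a, on chromosome 2 from 22580001 to 22590000, had 35, 8 and 0 in M and 11, 0 and 0 in RS. Whether the reads in these 2 bins came from these places in the genome was not tested, so the fall need not be a loss of nucleosomes there.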
